A study of Mus musculus with 8 samples.

How the data were processed

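RNA was measured by sequencing of mesenchymal cells sorted from embryonic mouse lung; the labels also call the tissue bulk lung. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with a Takara SMARTer v4 kit and Nextera XT, which carry no molecular identifiers. The 8 libraries comprised 4 controls and 4 conditional Sin3a knockouts (Sin3a CKO), and group and replicate number were taken from the sample titles. Per the submitters' processing notes, the mouse build mm10, STAR 2.5.3a, RSEM 1.3.0 and edgeR were used, without a role for each. The authors deposited 1 table of RSEM expected counts per gene, with 51912 genes and 8 value columns. Values in that deposited table were whole numbers in 100% of cells, so rounding the expected counts changed nothing. The annotation release and the use of strand in counting are not given in the sources used here, so overlapping and antisense genes cannot be told apart. Of the gene identifiers 51719 were found in GENCODE M21 on GRCm38 (mm10), which supplied 1-based coordinates, biotypes, exon lengths and GC content. Symbols on more than 1 line, 200 lines in all, were told apart by identifier.

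Totals ranged from 96098322 to 108493347 counts per library. Counts without molecular identifiers include PCR copies. Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr with a minimum count of 10, which left 20315, and libraries were scaled by TMM. Changes were tested with edgeR's 2-sided quasi-likelihood test with robust dispersions and group as the only term, and a Benjamini-Hochberg adjusted p under 0.05 counted as a call. Fold changes are on the log2 scale, Sin3a CKO over control, with a standard error (SE) equal to the absolute change divided by the square root of the F statistic. Levels are counts per M counts (CPM, M for mega) on TMM-scaled library sizes, as mean ± SD over 4 libraries.

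Gene lists were tested with camera at a preset correlation of 0.01 between genes, 2-sided and adjusted over 31 lists with at least 5 tested members. The lists comprise 24 groups chosen from the tissue and the deleted gene and 7 marker groups of other cell types, and 692 of their 754 genes were tested. Lists, tests and the rule for named genes were fixed before the data were examined. That rule took Sin3a and Sin3b, and the 5 largest called rises and 5 largest called falls. Those needed a mean of at least 5 CPM, no overlap between groups and a symbol other than a Gm number, a Rik clone, an identifier or a pseudogene. It also took the 2 members with the smallest p moving with each list past camera, and the called member with the smallest p of each other list, giving 59 genes, 3 of which are not reported here. Any other gene given by name was chosen after its values were seen.

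The gene test was tested on simulated data for this comparison, over 19423 genes with 100 genes changed 1.5-fold and 100 changed 2-fold. It recovered 33% and 69% of them, and 6.42% of all calls were false. Few genes changed in the simulation, in directions drawn at random, whereas 33.4% of tested genes were called in the data. Both shares can therefore differ in the real comparison. With simulated lists over 19417 genes, camera called the 1 list shifted 1.5-fold and 0 of the others. Simulated genes were drawn independently of each other, so this does not test the preset correlation, on which the list calls depend.

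Alternatives chosen before the data were examined were RLE and upper-quartile scaling, no filter, a mean of at least 10 CPM, DESeq2 1.42.0, limma-voom, unrounded counts, a block for replicate number, a block for identifier prefix, and each library left out in turn. For lists they also included an estimated correlation and fry. Identifiers in the labels begin with s686 (Control 1, Control 2 and Sin3a CKO 4), s1244 (Control 3 and Sin3a CKO 1, 2 and 3) or s722 (Control 4); what these prefixes stand for is not given in the sources used here. Control 4 alone has s722, so the block for prefix also takes it out of the comparison between groups. Within-prefix values set knockouts against controls of prefix s686 or of prefix s1244, each with 1 library on a side, so they have no test. Xist, a transcript of female cells, was at 174 and 184 CPM in Control 1 and 2 and 139 and 117 CPM in Sin3a CKO 1 and 3. In the other libraries it was at most 0.185 CPM, so each group held both sexes. Within s686, female controls are set against a male knockout, and within s1244 a male control against knockouts of both sexes. Sex was not a term in any fit. Removal of length and GC trends, an epithelium marker covariate and omission of Control 4 and Sin3a CKO 3 were chosen after seeing the data. Retrocopies were sought with BLAST 2.17.0 among tested pseudogenes and Gm-numbered genes, at 95% identity over 80% or more of the longest transcript, against coding transcripts of a gene on another chromosome.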

Results

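The transcriptome of lung mesenchymal cells was measured at embryonic day 16 in mice with conditional deletion of Sin3a, which encodes a scaffold of histone deacetylase corepressor complexes. In this line Tbx4-driven rtTA turns on a tetO-Cre transgene under doxycycline, fed to the mothers from embryonic day 12. Sin3a CKO embryos carried a pair of floxed Sin3a alleles and controls 1 floxed and 1 wild-type allele. By genotype, then, the design compares deletion of both alleles with deletion of 1, but the labels do not show how far deletion went. Each group had 4 libraries labelled as biological replicates, with 96098322 to 108493347 counts each. Genes above 0 counts ran from 25015 in Control 4 to 33188 in Sin3a CKO 2. The first principal component of log2 CPM, the main axis of variation among libraries (34.9% of variance), did not separate the groups. On it Control 3 was at 26.9 and Sin3a CKO 4 at -2.3, with Control 4 at -114.9. The design asked which genes differ between the groups at this stage.

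In Sin3a CKO mesenchyme 19 of 27 smooth muscle and 23 of 39 matrix genes fell, while 26 of 46 DNA replication and 13 of 24 SIN3 and HDAC complex genes rose. These 4 lists were past camera, a gene set test, at a preset correlation between genes, but each had adjusted p = 0.52 with an estimated correlation. Des, which encodes the muscle intermediate filament desmin, fell by 1.99 ± 0.20 on the log2 scale (SE, 4 against 4 libraries). Tnc, which encodes the matrix protein tenascin C, fell by 1.49 ± 0.17. Ing2, a chromatin-binding subunit of SIN3 complexes, rose by 1.35 ± 0.08, and Chaf1b, a subunit of the chromatin assembly factor used at replication, rose by 1.17 ± 0.11. For each of these 4 genes, named for a small p in this same comparison, all 4 knockout libraries lay beyond all 4 controls. That held for 6296 of the 6792 called genes, so it is no separate evidence.

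Sin3a (ENSMUSG00000042557, chromosome 9, 57072040 to 57128366, GRCm38) had 53.7, 46.8, 46.2 and 58.7 CPM in Control 1 to 4 and 56.6, 61.0, 53.2 and 61.0 CPM in Sin3a CKO 1 to 4. The means were 51.4 ± 5.94 and 58.0 ± 3.78 CPM, a log2 fold change of 0.17 ± 0.09 that did not pass edgeR's quasi-likelihood test (adjusted p = 0.191). The deleted exons are not given in the sources used here, and counts over the whole gene can include reads outside them, so this level does not check the genotype. With a block for identifier prefix the fold change was 0.29 with an adjusted p of 0.0332, within a range of 0.0264 to 0.706 over all alternatives. Its paralog Sin3b (ENSMUSG00000031622, chromosome 8, 72723285 to 72758201) rose by 0.56 ± 0.08 (adjusted p = 0.000688), from 123.9 ± 8.05 to 183.2 ± 15.8 CPM.

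**Figure D1:**
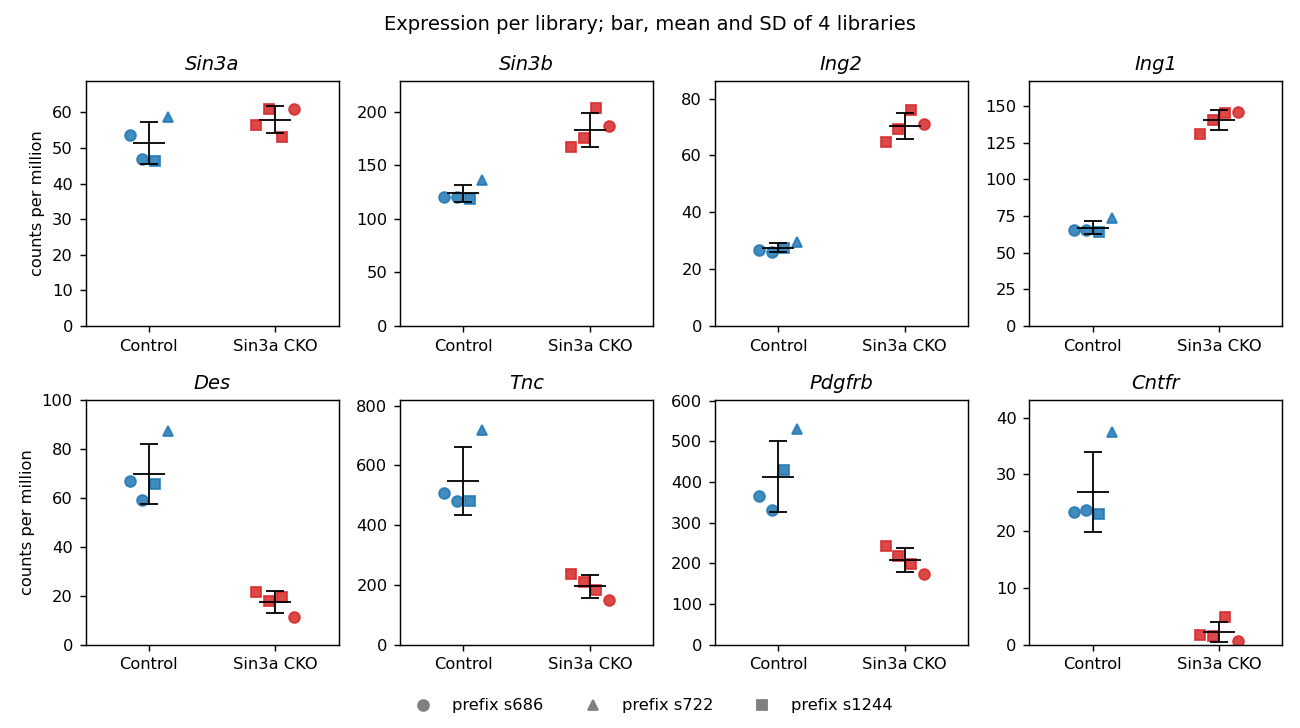
CPM of 8 genes in each library, with symbols for the identifier prefix and bars for the mean and SD of 4 libraries per group. Sin3a overlaps between the groups, at 46.2 to 58.7 CPM in controls and 53.2 to 61.0 CPM in knockouts, whereas the other 7 genes separate, as 6296 of the 6792 called genes do.

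Of 20315 genes tested, 3518 rose and 3274 fell in Sin3a CKO by edgeR's quasi-likelihood test, together 33.4%. At 2-fold or more 530 rose and 1385 fell, and at 4-fold or more 54 rose and 332 fell. The median called rise was 0.57 and the median called fall -0.86 on the log2 scale. The groups did not overlap for 6296 called genes, and for 36.1% of all tested genes, where chance gives 2.86%. The balance of directions depended on the filter and on scaling. Without a filter 2233 genes were higher and 3823 lower. Upper-quartile scaling, which moved the median change by -0.11, gave 2790 higher and 4522 lower, a higher share of 38.2% against 51.8% with TMM. With a block for prefix 3939 genes were higher and 3306 lower, and 5876 of the 6792 calls were kept in the same direction.

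**Figure D2:**
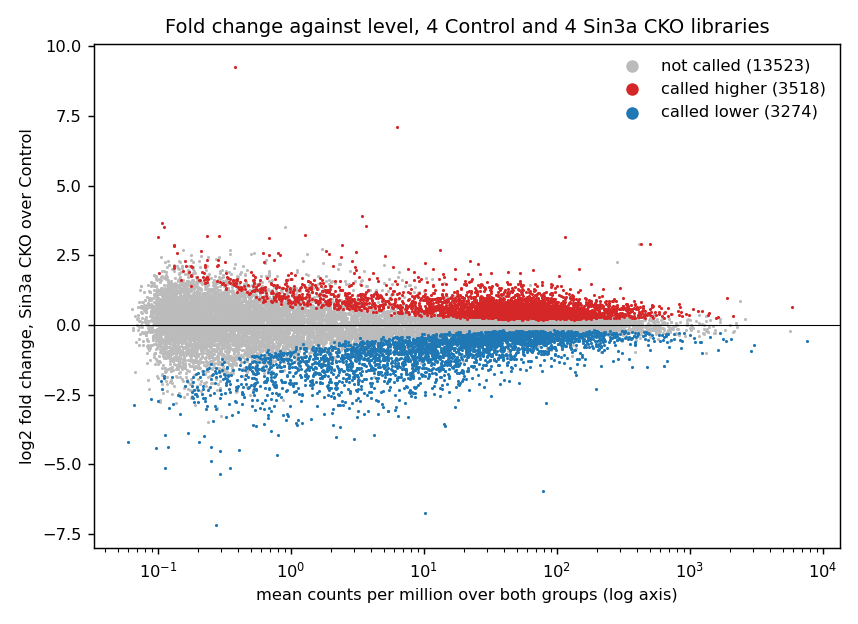
Fitted log2 fold change of Sin3a CKO over control against mean CPM on a log axis, 1 point per tested gene. Red points are the 3518 genes called higher and blue points the 3274 called lower.

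Of 24 tested SIN3 and HDAC complex genes 13 rose and 11 did not pass; adjusted over the list alone 14 rose and 1 fell. Ing2 went from 27.5 ± 1.57 to 70.2 ± 4.60 CPM, and Ing1, a related reader of histone methylation, rose by 1.07 ± 0.07. Sap30 and Sap30l, which encode other SIN3 subunits and were chosen after their values were seen, rose by 1.46 ± 0.11 and 1.17 ± 0.10. The deacetylases Hdac1, at 0.16 ± 0.07, and Hdac2, at 0.04 ± 0.08, did not pass. The list median was 0.40, with 0.51 within prefix s686 and 0.44 within prefix s1244. It was past camera (adjusted p = 3.23e-08), with adjusted p = 0.52 with an estimated correlation.

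Of 46 DNA replication and S phase genes 26 rose and 20 did not pass, and 29 rose adjusted over the list alone. Besides Chaf1b, Dscc1, part of an alternative clamp loader, rose by 1.04 ± 0.11. Ccne1 (cyclin E) and E2f1, an S phase transcription factor, both chosen after their values were seen, rose by 1.15 ± 0.13 and 0.66 ± 0.10. The median was 0.34 (0.50 and 0.41 within prefixes s686 and s1244), and the list was past camera (adjusted p = 1.92e-08), with adjusted p = 0.52 with an estimated correlation. Of 48 mitosis and G2/M genes 7 rose and 41 did not pass (3 rose adjusted over the list alone), with Cdca3, a regulator of mitotic entry, at 0.53 ± 0.10. That list was not past camera (adjusted p = 0.264); its median of 0.05 was -0.05 under upper-quartile scaling, and it was past camera as higher with a block for prefix (adjusted p = 2.45e-05) but not without Control 4 alone (adjusted p = 0.0541).

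Of 7 CDK inhibitor genes 4 rose and 3 did not pass, also when adjusted over the list alone. Cdkn2d, which encodes an INK4 inhibitor, rose by 1.03 ± 0.09, and Cdkn3, a phosphatase acting on CDKs, rose by 0.95 ± 0.12. Cdkn1a, a p53 target chosen after its value was seen, was at 0.17 ± 0.20 and did not pass. The median was 0.58 (0.56 and 0.64 within prefixes s686 and s1244). The list was past camera (adjusted p = 0.00843), with adjusted p = 0.49 with an estimated correlation. Of 28 p53 target genes 10 rose, 3 fell and 15 did not pass (10 and 4 adjusted over the list alone), and the list was not past camera (adjusted p = 0.0629), but was with a block for prefix (adjusted p = 0.0316) and without Control 4, Sin3a CKO 1, Sin3a CKO 2 or Sin3a CKO 3 (adjusted p = 0.0495, 0.0455, 0.0373 and 0.0443). Aen, an apoptosis-enhancing nuclease, rose by 1.17 ± 0.10. Fas and Bax, which promote apoptosis, rose by 1.09 ± 0.11 and 0.96 ± 0.10, and Mdm2, which encodes the p53 ubiquitin ligase, fell by 0.41 ± 0.09, all 3 chosen after their values were seen.

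Of 51 oxidative phosphorylation genes 26 rose, 1 fell and 24 did not pass (28 and 1 adjusted over the list alone). Atp5g1, an ATP synthase subunit, rose by 0.87 ± 0.10, and Ndufa1, a complex I subunit, rose by 0.92 ± 0.11, or by 0.34 ± 0.05 with length and GC trends removed. Sdha, a complex II subunit chosen after its value was seen, fell by 0.23 ± 0.07. The median of 0.29 was 0.09 within prefix s686 and 0.32 within prefix s1244, and the list was past camera (adjusted p = 1.11e-05), with adjusted p = 0.60 with an estimated correlation. The median was 0.12 with length and GC trends removed and 0.15 without Sin3a CKO 3 (adjusted p = 0.0201 and 0.00133). Mitochondrially encoded transcripts took 0.823% ± 0.117 (SD, n = 4) of counts in controls and 1.21% ± 0.0545 in knockouts, without overlap.

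Of 27 smooth muscle and myofibroblast genes 19 fell and 8 did not pass, also when adjusted over the list alone. Des went from 69.6 ± 12.3 to 17.5 ± 4.45 CPM, and Cnn1, which encodes calponin, fell by 1.48 ± 0.16. Acta2, smooth muscle actin, chosen after its value was seen, was at -0.06 ± 0.12 and did not pass. Of 14 pericyte genes 7 fell and 7 did not pass (8 fell adjusted over the list alone). Rgs5, a regulator of G protein signalling, fell by 1.46 ± 0.18, and Pdgfrb, a PDGF receptor, fell by 0.99 ± 0.15. The medians were -0.68 for smooth muscle (-0.81 and -0.50 within prefixes s686 and s1244) and -0.71 for pericytes (-1.20 and -0.71). Both were past camera (adjusted p = 1.92e-08 and 0.000329), and both had adjusted p = 0.52 with an estimated correlation.

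Of 39 matrix and elastic fibre genes 23 fell and 16 did not pass (25 fell adjusted over the list alone). Besides Tnc, Loxl2, which encodes a collagen crosslinking enzyme, fell by 1.22 ± 0.15. Col1a1 and Eln, which encode collagen I and elastin and were chosen after their values were seen, were at -0.92 ± 0.14 and -0.91 ± 0.23. Of 12 cartilage genes 3 fell and 9 did not pass, also when adjusted over the list alone, among them the cartilage collagen genes Col9a2 at -1.67 ± 0.14 and Col11a1 at -1.14 ± 0.17. The medians were -0.52 for matrix genes (-0.51 and -0.43 within prefixes s686 and s1244) and -0.56 for cartilage genes (-0.44 and -0.47, and -0.37 without Sin3a CKO 2). Both lists were past camera (adjusted p = 4.77e-09 and 0.00406), and both had adjusted p = 0.52 with an estimated correlation.

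Of 21 alveolar fibroblast and lipofibroblast genes 9 fell, 1 rose and 11 did not pass (10 and 1 adjusted over the list alone). Gdf10, which encodes a BMP family ligand, fell by 0.98 ± 0.09, and Lpl, lipoprotein lipase, was at -0.91 ± 0.10. Of 17 adventitial fibroblast genes 7 fell, 1 rose and 9 did not pass (9 and 2 adjusted over the list alone). Igfbp4, which encodes an IGF binding protein, was at -1.22 ± 0.10 and Clec3b, tetranectin, at -1.65 ± 0.17, while Ccl11, the chemokine eotaxin, chosen after its value was seen, was at 0.88 ± 0.10. The medians were -0.28 (-0.22 and -0.34 within prefixes s686 and s1244) and -0.81 (-0.93 and -0.86). Both lists were past camera (adjusted p = 0.00441), and both had adjusted p = 0.52 with an estimated correlation.

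Of 32 Wnt signalling genes 17 fell, 1 rose and 14 did not pass (18 and 1 adjusted over the list alone), and of 34 TGF-beta and BMP genes 19 fell, 2 rose and 13 did not pass (21 and 2). Nkd2, an inhibitor of Wnt signalling, was at -1.40 ± 0.15, Sfrp2, a secreted Wnt modulator, at -0.94 ± 0.10 and Tgfb3, a TGF-beta ligand, at -0.94 ± 0.11. The medians were -0.48 (-0.42 and -0.35 within prefixes s686 and s1244) and -0.50 (-0.35 and -0.40). Both were past camera (adjusted p = 1.49e-05 and 0.000172), and both had adjusted p = 0.52 with an estimated correlation. Of 11 Hedgehog genes 6 fell and 5 did not pass, also when adjusted over the list alone, with the coreceptor gene Boc at -0.64 ± 0.15, or -0.39 ± 0.08 with a block for prefix. The Hedgehog median was -0.44 (-0.24 and -0.32), past camera (adjusted p = 0.00965) but with adjusted p = 0.54 with an estimated correlation, and the call ended with a block for prefix (median -0.26, adjusted p = 0.0746). Gli1 and Ptch1 of the Hedgehog list, chosen after their values were seen, were at -0.003 ± 0.121 and -0.258 ± 0.138 and did not pass. Axin2 and Nkd1 of the Wnt list, chosen likewise, were at 0.03 ± 0.161 and -0.033 ± 0.106 and did not pass. The lists group genes by pathway, and the Wnt list includes inhibitors such as Nkd2. Their medians therefore do not measure pathway activity, which was not tested.

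Of 18 FGF genes 7 fell, 1 rose and 10 did not pass (8 and 1 adjusted over the list alone), with the receptor Fgfr1 at -0.73 ± 0.12 and the feedback inhibitor Spry1 at -0.95 ± 0.17. Camera's adjusted p was 0.0479 (median -0.29, within prefixes -0.22 and -0.19), with adjusted p = 0.60 with an estimated correlation. The FGF call ended without Control 4, Sin3a CKO 2 or Sin3a CKO 4 (adjusted p = 0.0513, 0.0601 and 0.0547). That call also ended with fry, a block for replicate number, the epithelium covariate, and without Control 4 and Sin3a CKO 3 together. Of 17 retinoic acid genes 7 fell, 1 rose and 9 did not pass (8 and 1 adjusted over the list alone), with the receptor Rarb at -0.73 ± 0.12 and the retinol transporter Stra6 at -2.34 ± 0.58, or -3.11 ± 0.51 without Sin3a CKO 3. Camera's adjusted p was 0.0455 (median -0.35, within prefixes -0.39 and -0.17), with adjusted p = 0.52 with an estimated correlation. The call ended with a block for prefix (median -0.23, adjusted p = 0.123) and without Control 1, Sin3a CKO 1 or Sin3a CKO 2 (adjusted p = 0.0601, 0.0663 and 0.0677). That call also ended with a mean of at least 10 CPM, a block for replicate number and the epithelium covariate. Of 20 vascular signalling genes 6 fell, 1 rose and 13 did not pass, also when adjusted over the list alone, with Ptgis, prostacyclin synthase, at -1.94 ± 0.18 and the angiopoietin Angpt2 at -0.75 ± 0.14. Camera's adjusted p was 0.0397 (median -0.28, within prefixes -0.25 and -0.16), with adjusted p = 0.54 with an estimated correlation, and the call ended without Sin3a CKO 2 (adjusted p = 0.0601). That call also ended without Control 4 and Sin3a CKO 3 together. Endothelium markers had a median of -0.43 (camera adjusted p = 0.223), and of -0.77 without Control 4 (adjusted p = 0.00239).

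Of 19 immediate early genes 5 fell and 14 did not pass (3 fell adjusted over the list alone). Nr4a1, a nuclear receptor, was at -2.29 ± 0.60, with 136.5 to 779.5 CPM in controls. It was at -1.47 ± 0.30 without Control 4 and -1.22 ± 0.28 with a block for prefix. Its call ended without a filter (-2.36 ± 0.67, adjusted p = 0.0749), without Sin3a CKO 2 (adjusted p = 0.0632) and with the epithelium covariate (-1.67 ± 0.75, adjusted p = 0.147). Hspa1a, a heat shock gene whose near-identical neighbour makes its count uncertain, was at -0.85 ± 0.22. Of 13 germline genes 5 fell, 1 rose and 7 did not pass, also when adjusted over the list alone, with the meiotic cohesin gene Stag3 at -1.49 ± 0.18 and Zcwpw1, a histone reader of meiosis, at -0.72 ± 0.09. The medians were -0.87 (-0.37 and -0.41 within prefixes s686 and s1244) and -0.76 (-1.16 and -0.70). Both lists were past camera (adjusted p = 0.00406 and 0.0164), with adjusted p = 0.61 and adjusted p = 0.49 with an estimated correlation. The immediate early median was -0.54 without Control 4 and -0.35 with a block for prefix.

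**Figure D3:**
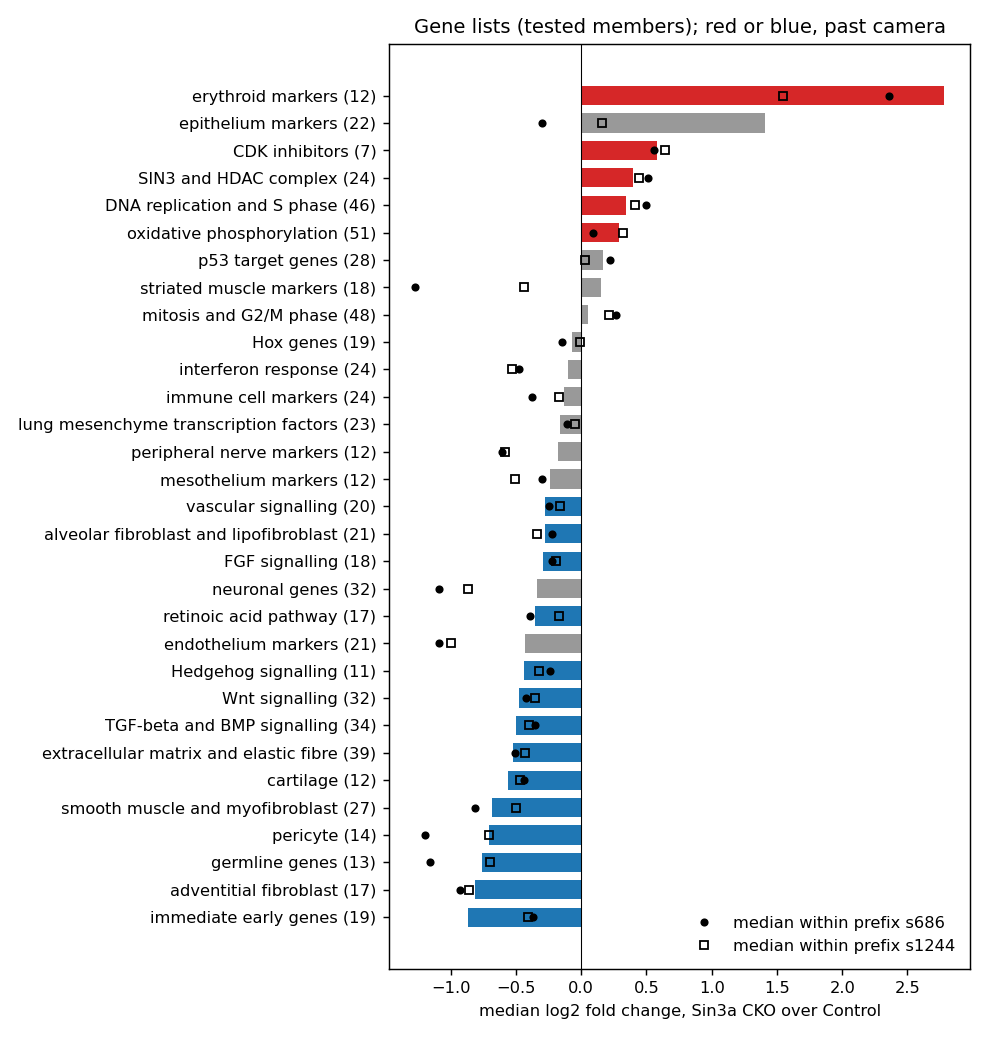
Median log2 fold change of Sin3a CKO over control for 31 gene lists, with tested members in brackets, red or blue bars for lists past camera, grey bars for the others, and markers for the medians within prefixes s686 and s1244. Erythroid markers stand highest at 2.78 and immediate early genes lowest at -0.87.

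A further 4 developmental and response lists were not past camera. Of 23 lung mesenchyme transcription factors 3 rose and 8 fell, also when adjusted over the list alone (adjusted p = 0.124, and 0.0435 as lower without Sin3a CKO 3), with the homeobox gene Prrx2 at -1.12 ± 0.16. Of 19 Hox genes 3 rose and 4 fell, also when adjusted over the list alone (adjusted p = 0.826), with Hoxb4 at 0.56 ± 0.12. Of 32 neuronal genes 2 rose and 7 fell, also when adjusted over the list alone (adjusted p = 0.0761, and as lower 0.00452 with a block for prefix, 0.0152 without Control 4 and 0.0311 without Sin3a CKO 2), with the neurofilament gene Nefm at -2.44 ± 0.38. Of 24 interferon response genes 3 rose and 4 fell, also when adjusted over the list alone (adjusted p = 0.868).

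Transcripts of other cell types differed among libraries. Of 12 erythroid markers 6 rose and 6 did not pass (7 rose adjusted over the list alone), with the alpha globin gene Hba-a1 at 2.91 ± 0.64. Globin genes have near-identical copies, so their separate counts are uncertain. Haemoglobin transcripts took 0.0358% ± 0.0386 (SD, n = 4) of counts in controls and 0.255% ± 0.126 in knockouts. The list median was 2.78 (2.36 and 1.55 within prefixes s686 and s1244, 1.96 with a block for prefix and 3.57 without Control 3), past camera (adjusted p = 0.00406) with adjusted p = 0.52 with an estimated correlation. Hbb-bs, a beta globin gene at 2.90 ± 0.75, lost its call without Control 1, Control 2 or Sin3a CKO 3 (adjusted p = 0.0617, 0.0617 and 0.0586). Without a filter Hbb-bs and Hba-a1 both lost their calls (edgeR adjusted p = 0.0947 and 0.0539).

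Epithelium transcripts followed the identifier prefix. Sftpc, which encodes a surfactant protein, was at 297 CPM in Control 3 and 466, 311 and 1050 CPM in Sin3a CKO 1, 2 and 3, all of prefix s1244, and at 31.4, 34.7 and 30.1 CPM in Control 1, 2 and 4 and 30 CPM in Sin3a CKO 4. Of 22 epithelium markers 1 rose, the transcription factor gene Elf5 at 2.59 ± 0.67, and 0 adjusted over the list alone; the list was not past camera (adjusted p = 0.0559), but was without Control 3, Sin3a CKO 2 or Sin3a CKO 4 (adjusted p = 7.87e-05, 0.0364 and 0.00098), and its median of 1.41 was -0.30 and 0.16 within prefixes s686 and s1244. Elf5 was at 1.86 ± 0.61 without Sin3a CKO 3 and lost its call with a block for prefix (1.71 ± 0.74, adjusted p = 0.108) and with the epithelium covariate (1.42 ± 0.61, adjusted p = 0.106). Control 4 had 1.04 CPM of Pecam1, an endothelial gene, and 0.304 CPM of Ptprc, a pan-leukocyte gene, against 10.6 to 33.1 and 3.86 to 9.73 CPM in the other libraries. Of 21 endothelium markers 2 fell, also when adjusted over the list alone, with Ramp2 at -1.46 ± 0.26. That list was not past camera (adjusted p = 0.223), and its median of -0.43 was -1.09 and -1.0 within prefixes s686 and s1244. It was past camera as lower without Control 4 alone (median -0.77, adjusted p = 0.00239), and with a block for prefix, which also takes Control 4 out of the comparison (median -1.01, adjusted p = 7.54e-09).

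Of 24 immune cell markers 0 were called by edgeR, DESeq2 or limma-voom, and 0 had an unadjusted p under 0.05; camera pointed up (adjusted p = 0.641) where the median and mean were -0.13 and -0.04. Without Control 4 that list was past camera as lower (median -0.58, adjusted p = 0.0203). Of 12 mesothelium markers 2 fell (1 adjusted over the list alone; camera adjusted p = 0.416), with Rspo1, a Wnt agonist gene, at -0.99 ± 0.21. Of 12 peripheral nerve markers 3 fell, also when adjusted over the list alone (camera adjusted p = 0.253), with the neurotrophin receptor gene Ngfr at -2.82 ± 0.34. Of 18 striated muscle markers 3 fell, also when adjusted over the list alone (camera adjusted p = 0.315), with Neb, which encodes nebulin, at -3.39 ± 0.41; the median was 0.15 where the mean was -0.07 and camera pointed down.

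**Figure D4:**
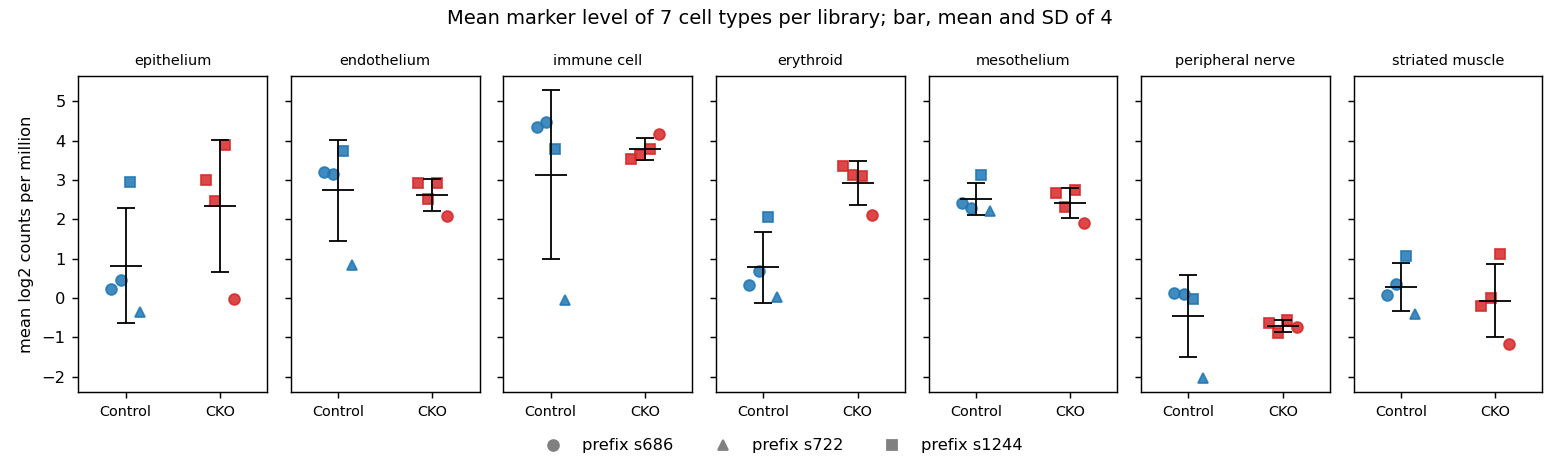
Mean log2 CPM of the markers of 7 cell types in each library, with symbols for the identifier prefix and bars for the mean and SD of 4 libraries per group. Erythroid markers lie between 0.04 and 2.06 in controls and between 2.11 and 3.35 in knockouts.

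Under the rule for named genes, 4 of the 5 largest rises were the globin and haem synthesis genes Hbb-bt at 3.16 ± 0.73, Hba-a1, Hbb-bs and Alas2 at 2.69 ± 0.67. These 4 were at 4.14, 3.76, 3.99 and 3.77 without Control 3, and at 2.37, 2.23, 2.14 and 2.01 with a block for prefix. Without a filter all 4 lost their calls (edgeR adjusted p = 0.0639, 0.0539, 0.0947 and 0.0951). The other was Cyp46a1 (ENSMUSG00000021259, chromosome 12, 108334381 to 108362234), which encodes a cholesterol hydroxylase and rose by 2.31 ± 0.16, from 7.46 ± 1.35 to 37.0 ± 6.43 CPM. The 5 largest falls were Cntfr (ENSMUSG00000028444, chromosome 4, 41657498 to 41697089), the ciliary neurotrophic factor receptor gene, at -3.63 ± 0.55, the muscle glycogen phosphorylase gene Pygm at -3.55 ± 0.34, Exoc3l4 at -3.30 ± 0.36, Notum, which encodes a secreted Wnt deacylase, at -3.27 ± 0.45, and Bcat1, a branched-chain aminotransferase gene, at -3.10 ± 0.26. Without Sin3a CKO 3, Cntfr was at -4.39 ± 0.36 and Notum at -3.88 ± 0.32.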

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

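All tests of explanations in this part were chosen after the results were seen. In 16 of 136 groups of 4 libraries, 1 library stood far from the other 3, where chance flags about 1 in 20 groups. Control 4 stood above the other controls in Sin3b at 136 CPM, Cntfr at 37.4 CPM, Ing1 at 73.9 CPM, Tnc at 717 CPM, Loxl2 at 292 CPM and Prrx2 at 40.7 CPM. It stood below them in the mean log2 CPM of immune cell markers at -0.0562 and of peripheral nerve markers at -2.02. Control 3 had Chaf1b at 53.2 CPM, below the other controls. Control 2 had Exoc3l4 at 11.6 CPM, below the other controls, and Nefm at 6.99 CPM, above them. Sin3a CKO 4 had Tgfb3 at 43.8 CPM, below the other knockouts, and Sin3a CKO 1 a total of 106 M counts, above them. Control 3 also stood above the other controls in Hbb-bs at 307 CPM, Alas2 at 9.18 CPM and a haemoglobin share of 0.093% of counts.

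Of 12 erythroid markers 6 rose in Sin3a CKO, with adjusted p = 0.52 for the list with an estimated correlation. A difference between identifier prefixes as the whole source is argued against by 5 of 5 erythroid genes at 5 CPM or more being called higher with a block for prefix, with Hbb-bs at 2.14 ± 0.22 (SE); 4 of them were called without it, and Hba-a2 was not (2.91 ± 0.97, adjusted p = 0.0542). The erythroid level rose relative to endothelium, mesothelium, nerve and striated muscle markers (adjusted p = 0.0429 for each, 2-sided exact permutation tests, 6 in all). Relative to epithelium and immune markers it did not separate the groups (adjusted p = 0.343 and 0.309). The erythroid level already separated the groups and enters all 6 tests. They therefore do not decide whether cells outside the mesenchyme rose in general. More red cells carried through the sort and a change in the lung due to Sin3a loss both stay open, and neither was tested.

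Other splits of the 8 libraries into 4 and 4 were compared with the real one. As many genes higher as the real 3518 came from 1 of 35 splits, the real one, and the highest of the others was 69 in 1 direction. For the 3274 genes lower it was also 1 of 35, with a highest other of 69. The real split thus called far more genes than the others, but these splits cannot exclude chance. The smallest share possible is 1 of 35, and the splits ignored the identifier prefix. Every other split also mixed controls with knockouts, which adds the group difference to the spread within groups. The other split with most calls, 70 in both directions, set the 4 libraries of prefix s1244 against the rest. For lists, the direction with more lists was counted in each other split. As many as the 5 higher came from 35 of 35 splits, which was nearly fixed, since 5 is the smaller direction of the real split. As many as the 14 lower came from 7 of 35, with up to 16 in another split. Most of those other splits swapped 1 library between the groups and so kept part of the real difference. These counts of lists therefore decide nothing about chance, which cannot be excluded for either.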

How the results depend on the processing

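The fits with length and GC trends removed, with an epithelium marker covariate and without Control 4 and Sin3a CKO 3 were chosen after seeing the data. Sin3a, the named genes and the lists past camera kept their direction under every alternative that gave a value. The balance of gene counts did not: more genes were lower than higher with RLE (3302 higher and 3630 lower) and upper-quartile scaling, without a filter, with DESeq2, with length and GC trends removed, without Control 4 and Sin3a CKO 3 together, and without Control 2, Control 4, Sin3a CKO 3 or Sin3a CKO 4 alone. With each library left out in turn, 2653 to 3260 genes were higher and 2548 to 3723 lower, 5 to 7 lists were higher and 12 to 16 lower, and the Sin3a log2 fold change was 0.12 to 0.20. Without a filter 2233 genes were higher and 3823 lower; the cause was not tested. With an estimated correlation 0 lists were higher and 0 lower, and at an unadjusted p under 0.05 1 list was higher and 1 lower; fry had 6 higher and 12 lower, and the FGF and immediate early calls ended (adjusted p = 0.0703 and 0.125). With a mean of at least 10 CPM 3012 genes were higher and 2688 lower, and the retinoic acid call ended (adjusted p = 0.14). Without Control 4 and Sin3a CKO 3 the FGF and vascular calls ended (adjusted p = 0.0873 and 0.0617), as did those of Hbb-bs and Elf5 (adjusted p = 0.0847 and 0.0786). Sin3a passed the threshold as higher at 0.29 with a block for identifier prefix, 0.20 with length and GC trends removed, 0.27 with the epithelium covariate and 0.22 without Control 4 and Sin3a CKO 3 (adjusted p = 0.0332, 0.0264, 0.0389 and 0.0455); the cause was not tested. Those last 3 fits called 3720, 3791 and 3402 genes higher and 3838, 3172 and 3741 lower. With the replicate number as a block, 3560 genes were higher and 3222 lower, 7 lists higher and 12 lower, and Sin3a was at 0.18 (adjusted p = 0.123). The numbers do not pair the libraries: same-numbered libraries had residual correlations of 0.13, -0.40, 0.10 and 0.16, and 0 of 4 controls correlated best with their own number. Under that block the FGF and retinoic acid calls ended (adjusted p = 0.0584 and 0.0534), and the p53 target and epithelium lists passed as higher (adjusted p = 0.0187 and 0.000182). DESeq2 called 3770 genes higher and 4106 lower, and limma-voom 3557 and 3407, where Elf5 lost its call (adjusted p = 0.077). Without a filter 5 named genes lost their calls, Hbb-bt, Hba-a1, Hbb-bs, Alas2 and Nr4a1 (adjusted p up to 0.0951). Unrounded counts moved nothing, since the values were whole, and so test nothing.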

Other observations

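The gene families and the tests of explanations in this part were chosen after the data were seen. Genes were grouped by the letters that open their symbols into 140 families of 10 or more, of which camera put 16 higher and 12 lower at the preset correlation. With an estimated correlation camera put 0 of them past the threshold (adjusted p from 0.97), and 2 had an unadjusted p under 0.05. Log2 change fell with exon length over genes (Spearman's rho -0.172), and the families were not tested with length and GC trends removed. Of 48 Rpl genes, which encode ribosomal proteins, 43 rose and 1 fell (median 0.56, and 0.45 with upper-quartile scaling), with Rpl23 at 0.72 ± 0.10. Of 42 genes with Rps symbols 37 rose and 2 fell (median 0.56, and 0.46), with Rps10, a ribosomal protein gene, at 0.83 ± 0.09. The letters Rps also open the symbols of kinase genes, so these values are not those of ribosomal protein genes alone. For the Rpl and Rps families camera's adjusted p was 1.87e-14 and 1.39e-11, but adjusted p = 0.98 and adjusted p = 0.97 with an estimated correlation. Of 28 Polr genes, which encode RNA polymerase subunits, 20 rose and 2 fell, with Polr1e at 1.00 ± 0.09 (camera adjusted p = 0.000101, and adjusted p = 0.97 with an estimated correlation). Of 13 Snhg genes, hosts of small nucleolar RNAs, 10 rose, with Snhg5 at 0.79 ± 0.10 (camera adjusted p = 0.00264, and adjusted p = 0.97 with an estimated correlation).

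Of 19 Pcdhb genes, which encode clustered protocadherins, adhesion proteins of neurons and other cells, 17 fell and 2 did not pass (median -1.24, and -1.34 with upper-quartile scaling), and of 12 Pcdhga genes, of the same kind, 9 fell and 3 did not pass (median -0.75). Camera's adjusted p was 7.4e-09 and 0.00343, and both families had adjusted p = 0.97 with an estimated correlation. Pcdhb3 was at -2.86 ± 0.24 and Pcdhb5 at -1.40 ± 0.16. Members of these families share sequence, as ribosomal protein genes do with processed copies, so their separate counts are uncertain.

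Gm9008 (chromosome 6, 76495432 to 76497784), 99.1% identical to Rnf26, fell by 6.72 ± 0.19, and Gm26825 and Gm15459, which overlap on chromosome 5 and are 99.6% and 99.7% identical to Hspa8, were at -5.96 ± 0.23 and -2.81 ± 0.09. These were 3 of 5 retrocopies that fell 4-fold or more. The others, Gm17728 at -5.11 ± 1.15 and Rbpsuh-rs3 at -2.40 ± 0.79, have their parents Ppih and Rbpj on chromosomes 4 and 5, where linkage to Sin3a cannot account for them. Their control levels were low or variable, at 0.673 ± 0.317 and 6.745 ± 6.58 CPM, against 20.2 ± 2.21 CPM for Gm9008. A candidate explanation is that reads of Rnf26 and Hspa8, on chromosome 9 at 13 and 16.3 Mb from Sin3a, were assigned to these copies in controls through a variant linked to the Sin3a alleles, which would leave the sum of parent and copies level. In 1 of the 2 parents the sum lay within 2 SE of no change and over 2 SE from the change if only the copies fell. Hspa8 rose by 0.36 ± 0.08 alone (edgeR adjusted p = 0.0068) and with its copies was at 0.06 ± 0.08, where that change would be -0.30. Rnf26 did not rise alone (0.01 ± 0.10, edgeR adjusted p = 0.967) and with its copy was at -0.20 ± 0.10, where that change would be -0.21. Loss of transcription at the copies' own loci was not told apart from this, since the Rnf26 sum excludes neither. Over the controls 1.0%, 18.9% and 28.9% of other genes followed the parent as tightly as Gm9008, Gm26825 and Gm15459 did, each taken alone. Together, the overlapping Gm26825 and Gm15459 were at 25.1% (SD 0.3) of the Hspa8 level in controls and 1.5% (SD 0.036) in knockouts. Gm9008 was at 15.7% (SD 0.36) and 0.148% (SD 0.038) of the Rnf26 level. This tracking in controls does not decide between parent reads and transcription at the copies, since 18.9% and 28.9% of other genes followed Hspa8 as tightly as its copies did. The 2 copies together were not compared with other genes. An effect of Sin3a on the copies was not tested.

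Matrix, smooth muscle and signalling lists were past camera as lower and replication and respiratory lists as higher in Sin3a CKO, but 0 of 31 lists were past it with an estimated correlation (adjusted p from 0.49). Log2 change fell with exon length over 13896 genes, which are not independent replicates (Spearman's rho -0.172, and -0.024 after length and GC trends were removed). With these trends removed, 19 of the 19 lists past camera kept direction and side. The oxidative phosphorylation median moved from 0.29 to 0.12 with them removed, and Ndufa1 from 0.92 to 0.34, so part of that rise goes with the trends. With the epithelium marker level as a covariate, 16 of the 19 lists kept both. The Hedgehog, FGF and retinoic acid calls ended there (camera adjusted p = 0.0656, 0.0691 and 0.0749). The 19 lists had been selected for passing the same camera test on these libraries, which up to 16 lists passed in another split. Neither count therefore decides whether the trends or epithelial carry-over were the whole source. The mix of mesenchymal cell types, other carry-over and an effect of Sin3a loss stay open and were not tested.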
